A study of Mus musculus with 6 samples.

How the data were processed

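Small RNA libraries were made from total RNA of primary mouse peritubular myoid cells, 3 libraries from untreated cells and 3 from cells treated with 50 nM endothelin-1 (ET1) for 5 min at 37 °C. Per the labels' protocols, the cells were grown with 10% fetal bovine serum, RNA was extracted with TRNzol and libraries followed the BGI small RNA protocol. Bowtie2 and the mouse genome build mm10 were named, per the submitters' processing notes, without a version of the aligner. The annotation databases, the number of mismatches allowed and the treatment of tags that match several loci were not given in the sources used here. Tags of near-identical miRNAs, such as the let-7 family, may therefore have been split or assigned to a single member.

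Per the file headers, the authors deposited a table of tag counts for 61628 rows in the 6 libraries, with a second value per library headed TPM. From the values, the deposited TPM column was an RPM: the count scaled to the tags of all rows, with no correction for length. The ratio of that RPM to the deposited value lay between 0.9981 and 1.0032 for counts of at least 50, and a count of 0 was written as 0.001. Of the rows, 1573 were named as known mouse miRNAs, 17 of them typed as hairpin and 11 covering several miRNAs of identical or shared sequence. A further 60051 rows were piRNAs, Rfam families, predicted miRNAs and predicted piRNAs. The remaining 4 rows were totals for exons, introns, intergenic sequence and repeats, and held 44.31% to 61.38% of the tags of a library. They entered no fit, and only their shares of tags were tested.

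The authors' deposited comparison table, named for DEGseq, listed 1800 miRNA rows. Its read counts were the authors' sums over the 3 libraries of a group, and its expression values were the authors' group means of the RPM. Its log2 ratio, of ET1 over untreated, differed by a constant from the log2 ratio of the deposited pooled counts, the pooled value minus the deposited one being −0.6965 in every row with both values (tolerance 0.001). Its p-values and q-values were deposited without the settings that gave them. Pooled counts hold no term for the spread between libraries. In 16 rows the pooled counts of the deposited table differed from the sum of the per-library counts, which was lower in 14 of them and higher in 2. None of the 11 miRNAs called here was among them. The deposited RPM values were not tested, because the counts behind them were given.

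Library depth was 18127265 to 20895432 tags, of which 4381927 to 8651018 were known miRNA tags. Counting error is therefore small for an abundant miRNA, and the spread between libraries sets the precision. The labels do not say that the libraries came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. Every pair of libraries of a group differed by more than sampling noise (chi-square per degree of freedom from 402 to 1477), so none was taken for another library deposited again; this does not show that they came from separate cultures.

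Known miRNAs were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling over the known miRNA rows, the default expression filter with the group, a robust quasi-likelihood fit with the group as the only term, a two-sided test and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter kept 616 miRNAs. Levels are CPM of known miRNA tags after TMM scaling, given as mean ± SD of 3 libraries. The other rows were tested in the same way in a separate fit, which kept 2579 rows. Before the data were examined, 13 lists of miRNAs were fixed: smooth muscle and myogenic, mesenchymal, let-7, miR-17-92 and paralogs, the Dlk1-Dio3 imprinted cluster, stimulus-responsive, spermatogenic, miR-290 to miR-295, epithelial and Sertoli, haematopoietic, endothelial, other tissues, and non-canonical biogenesis. Lists with at least 3 tested members were compared with the remaining miRNAs by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Shares of tags were compared by exact permutation, which cannot give a p below 0.1 with 3 libraries against 3, and were adjusted over 30 quantities.

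The miRNAs named were set by a rule fixed before the data were examined: the 10 most abundant, up to 10 in each direction that passed the test with no overlap between groups, the most abundant member of each list, and the 5 highest and 5 lowest by the deposited log2 ratio among deposited calls with at least 10 counts in each library of a group. From the other rows, up to 2 in each direction that passed would have been named, and none passed. List members named beyond this rule were chosen after their values were seen. Positions are those of the precursor genes in the RefSeq annotation of GRCm38.p6, 1-based, and the exon and intron context is that of GENCODE M21 on the same strand.

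Alternatives were DESeq2 size factors, library sizes alone, no filter, a filter of at least 10 CPM in 3 libraries, the replicate number as a block, DESeq2 1.42.0, limma-voom, a fit without robust estimation, all rows fitted together, the more abundant arm only, and each library left out in turn. Added after the data were seen were fits without the 16 rows, with mature rows only and without predicted rows. Also added were fits with a loess correction for GC content (span 0.75), with that correction and the block, and with the share of known miRNA tags as a covariate. A GC value was available for 610 of 616 miRNAs. It was that of the 5p or 3p side of the precursor, or of the whole precursor where no arm was named, not that of the tags. Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

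The fits were tested on simulated counts with 200 changed rows. For the known miRNAs, 10.3% of changes of 1 log2 unit, 57.7% of changes of 2 and 98.3% of changes of 4 were recovered, with 2 of 407 unchanged miRNAs called. For the other rows, 0%, 3.85% and 44.2% were recovered at the same sizes, with 0 of 1905 unchanged rows called. These percentages are of the changed rows that passed the filter, 58, 71 and 60 known miRNAs and 50, 52 and 52 other rows by size. Changed rows lost to the filter were not counted. The 200 changed known miRNAs also outnumber the 11 calls here, which eases the adjustment, so recovery may be lower in these data.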

Results

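Small RNAs were counted in primary peritubular myoid cells, the contractile cells that surround the seminiferous tubules of the testis, from C57BL/6J mice. The groups were untreated cells (n = 3 libraries) and cells exposed for 5 min to 50 nM ET1 (n = 3 libraries), a peptide that makes smooth muscle contract. The design addresses the effect of ET1 on the small RNAs of these cells. Untreated libraries held 20895432, 18972157 and 20700178 tags, and ET1 libraries 18127265, 19414045 and 19493731 tags. Known miRNA tags numbered 8112210, 8651018 and 6240334 in the untreated libraries and 4628020, 4381927 and 4825429 in the ET1 libraries.

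Known miRNAs made up a smaller part of the ET1 libraries, 24.3% ± 1.53 of all tags against 38.2% ± 7.75 in untreated libraries (SD, n = 3 each; exact permutation p = 0.1, adjusted 0.375, two-sided). Fragments of rRNA made up 9.44% ± 2.05 of the ET1 tags against 4.55% ± 1.22 of the untreated tags, and those of the small ribosomal subunit RNA 4.23% ± 1.92 against 0.866% ± 0.372 (exact permutation p = 0.1 for each, adjusted 0.375). Tags from repeats made up 22.7% ± 1.38 against 18.2% ± 2.29, with the same exact p. In each of these classes the groups did not overlap, but 0.1 is the smallest p that 3 libraries against 3 allow. Within the known miRNAs the 10 most abundant held 59.1% ± 1.13 of the tags in ET1 libraries and 60.03% ± 1.57 in untreated libraries (exact permutation p = 0.6); the difference of −0.93 points was −0.19 without untreated library 2, −1.75 without untreated library 3, −1.58 without ET1 library 2 and −0.52 without ET1 library 3.

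**Figure D1:**
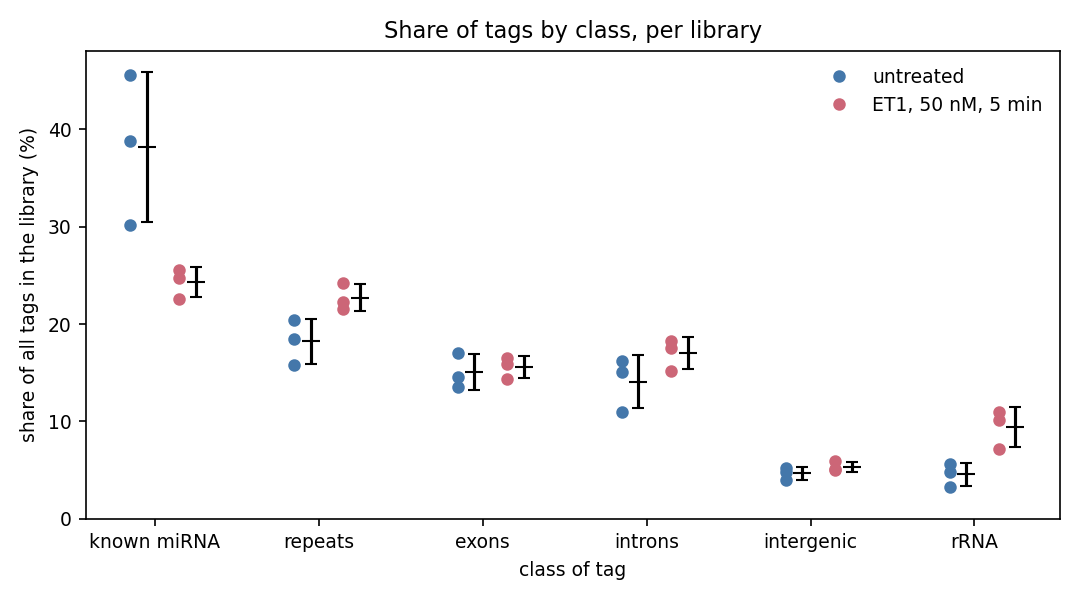
Share of all tags (%) in 6 classes, with a point per library (blue, untreated; red, ET1) and the group mean ± SD in black beside the points (n = 3). Known miRNA shares were 22.6% to 25.5% in the ET1 libraries and 30.1% to 45.6% in the untreated libraries.

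Among the 616 known miRNAs tested, 11 passed the threshold, 3 lower and 8 higher in the ET1 libraries, and in each of the 11 the groups did not overlap. miR-126a-3p, the main miRNA of endothelial cells, was 12.2-fold lower, at 131 ± 25.8 against 1602 ± 433.3 CPM (log2 fold change −3.61, SE 0.40; edgeR adjusted p = 0.00019). miR-150-5p, a miRNA of mature lymphocytes, was 10.9-fold lower, at 24.7 ± 4.59 against 270.4 ± 51.2 CPM (log2 fold change −3.45, SE 0.42; edgeR adjusted p = 0.00036). miR-10b-5p, encoded in the Hoxd cluster, was 3.62-fold lower, at 333 ± 107 against 1205 ± 327 CPM (log2 fold change −1.85, SE 0.39; edgeR adjusted p = 0.026), and did not pass without untreated library 2, ET1 library 2 or ET1 library 3. All n were 3 libraries per group.

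Of the 8 that rose, 3 came from the imprinted Dlk1-Dio3 cluster on chromosome 12. miR-540-3p reached 540 ± 298 against 127.2 ± 33.6 CPM (edgeR adjusted p = 0.032), miR-433-3p 1463 ± 260 against 495.3 ± 134.6 CPM (edgeR adjusted p = 0.045), and miR-3072-5p 6.71 ± 1.34 against 1.33 ± 0.608 CPM (edgeR adjusted p = 0.047). miR-296-3p and miR-298-5p, neighbours in the imprinted Gnas region, rose 4.31-fold, to 186 ± 59.7 from 43.2 ± 7.42 CPM, and 4.48-fold, to 131 ± 34.1 from 29.4 ± 5.85 CPM (edgeR adjusted p = 0.024 for both). The row shared by miR-486a-5p and miR-486b-5p, miRNAs of muscle and red cell precursors, rose 5.33-fold, to 823 ± 362 from 154.5 ± 77.8 CPM (edgeR adjusted p = 0.024). miR-5126 rose 5.23-fold, to 1594 ± 1154 from 305 ± 92.6 CPM (edgeR adjusted p = 0.032), and miR-1199-3p rose 7.13-fold, to 24.5 ± 11.5 from 3.41 ± 0.854 CPM (edgeR adjusted p = 0.013). After a correction for precursor GC content miR-5126, miR-1199-3p and miR-3072-5p no longer passed. Their log2 fold changes were 1.06, 1.59 and 1.73 in place of 2.39, 2.83 and 2.33. Without ET1 library 3 none of the 8 passed in edgeR, with miR-5126 at 1.65, and without untreated library 2 miR-1199-3p alone did.

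The precursor of miR-126a (GRCm38, chromosome 2, 26591357 to 26591429, plus strand) overlaps an exon of Egfl7, and that of miR-10b (chromosome 2, 74726070 to 74726137, plus strand) lies in an intron of Hoxd3. The precursor of miR-150 (chromosome 7, 45121757 to 45121821, plus strand) has no host gene on its strand. Mir298 (174267504 to 174267585) and Mir296 (174267047 to 174267125) lie on the minus strand of chromosome 2, with no annotated host gene on that strand. On the plus strand of chromosome 12, Mir540 (109586080 to 109586146) and Mir433 (109591715 to 109591838) have no host gene, and Mir3072 (109747878 to 109747960) overlaps an exon of Mirg. Mir486 (chromosome 8, 23142555 to 23142682, plus strand) lies in an intron of Ank1, Mir1199 (chromosome 8, 84011515 to 84011633, minus strand) overlaps an exon of 2210011C24Rik, and Mir5126 (chromosome 1, 84695839 to 84695915, plus strand) has no host gene.

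After TMM scaling the groups did not overlap for 23.5% of the 616 miRNAs. Barring ties, the mean of this share over all splits of the libraries into 3 and 3 is 10%. Because miRNAs vary together, a single split can exceed that mean without an effect of ET1. The share in the other splits was not computed. Of the miRNAs without overlap, 77 were higher and 68 lower in ET1 libraries. Of the 616 miRNAs, 113 had an unadjusted edgeR p under 0.05. The count of calls was 41 (38 higher and 3 lower) with library sizes alone, which moved the median log2 fold change of all tested miRNAs to 0.37, and 0 in edgeR with the share of miRNA tags as a covariate or with all rows fitted together (39 and 116 at an unadjusted p under 0.05). It was 5 without untreated library 2 (2 higher, 3 lower), 25 without untreated library 3 (15 higher, 10 lower), 30 without ET1 library 1 (21 higher, 9 lower), 9 without ET1 library 2 (4 higher, 5 lower) and 2 without ET1 library 3, both lower; miR-126a-3p and miR-150-5p passed in each of the 6 fits that left out 1 library, and each of the others was lost in 1 to 4 of them.

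**Figure D2:**
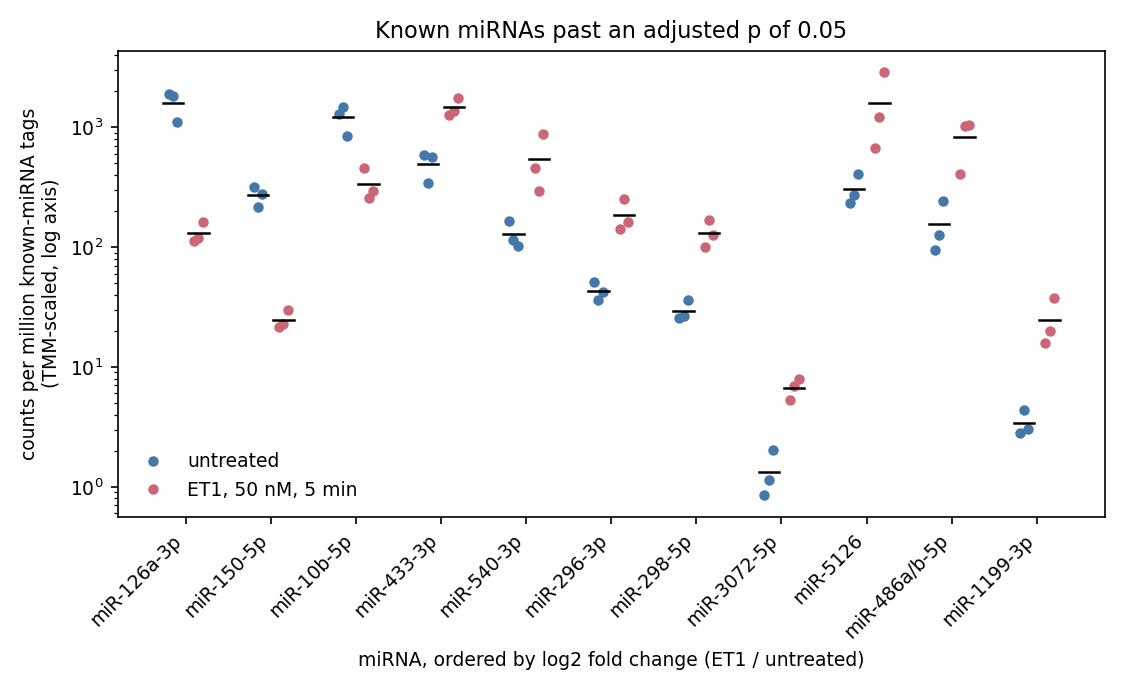
CPM of known miRNA tags after TMM scaling (log axis) for the 11 known miRNAs past an adjusted p of 0.05, ordered by log2 fold change, with a point per library (blue, untreated; red, ET1) and black lines at the means (n = 3). miR-126a-3p lay between 113 and 161 CPM in the ET1 libraries and between 1102 and 1876 CPM in the untreated libraries.

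None of the 10 most abundant miRNAs passed the test. let-7c-5p stood at 146269 ± 20595 CPM in ET1 and 198525 ± 55564 CPM in untreated libraries, and let-7b-5p at 119707 ± 11542 and 150938 ± 20314 CPM (edgeR adjusted p = 0.44 and 0.52). Their log2 fold changes were −0.44 and −0.33, and those of miR-652-3p and miR-470-5p, the latter a miRNA of the X chromosome expressed in testis, were −0.53 and 0.039. let-7a-5p (−0.94, SE 0.32, edgeR adjusted p = 0.11) and miR-22-3p (−0.65, SE 0.30, edgeR adjusted p = 0.26) did not pass. After TMM scaling both were lower in all 3 ET1 libraries than in any untreated library. TMM factors ran from 0.82 to 0.96 in untreated and from 1.08 to 1.18 in ET1 libraries. By library size alone the groups overlapped for both. Untreated library 3 held 163889 let-7a-5p and 164354 miR-22-3p tags of 6240334 known miRNA tags. ET1 library 1 held 131518 and 135857 of 4628020. The remaining members were miR-34a-5p, miR-181a-5p, miR-125b-5p and let-7d-3p, at log2 fold changes of −0.38, −0.34, −0.30 and 0.099. With 1 library left out, miR-34a-5p ran from −0.54 to −0.045, miR-181a-5p from −0.52 to −0.074, miR-125b-5p from −0.52 to −0.089 and miR-652-3p from −0.87 to −0.32. Without untreated library 3, let-7a-5p (−1.14) and let-7d-3p (1.07) passed. The sign of the values nearest to 0 followed the scaling, since the median of all tested miRNAs was 0.37 with library sizes alone, where let-7b-5p, miR-34a-5p, miR-181a-5p and miR-125b-5p were above 0, and −0.46 with all rows fitted together, where miR-470-5p and let-7d-3p were below 0.

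The fixed list of the Dlk1-Dio3 cluster, a set of maternally expressed miRNAs between positions 109563692 and 109747960 of chromosome 12, lay higher in the ET1 libraries. Of its 68 tested members, 56 had a positive and 12 a negative log2 fold change, with a median of 0.75. The 3 that rose were miR-540-3p, miR-433-3p and miR-3072-5p, none fell, and adjusted over the list alone 10 rose and 1 fell. miR-134-5p (1.59) and miR-485-3p (2.02) did not pass over all miRNAs (edgeR adjusted p = 0.079 for both; miR-485-3p passed without untreated library 3, at 2.56), and miR-127-3p, the most abundant member, was at −0.16, or 0.22 with library sizes alone (8710 ± 3801 against 9714 ± 578 CPM). The list passed camera's test (adjusted p = 1.54e-07 over 12 lists), but adjusted p = 0.38 with an estimated correlation, within a range of 3.91e-12 to 0.38 over 19 alternatives. In the same libraries the share of known miRNA tags was lower and that of rRNA fragments higher.

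The smooth muscle and myogenic list lay lower in the ET1 libraries, which also had a lower share of known miRNA tags and a higher share of rRNA fragments. Of its 7 tested members 6 had negative log2 fold changes, with a median of −1.23; none passed over all miRNAs, and adjusted over the list alone 3 fell. miR-143-3p, the most abundant, stood at 11789 ± 1506 against 22500 ± 4132 CPM (−0.93; edgeR adjusted p = 0.10; it passed without untreated library 3, at −1.06), and miR-133a-3p, a miRNA of striated muscle, at 83.2 ± 16.3 against 240.7 ± 24.2 CPM (−1.53; edgeR adjusted p = 0.072). miR-145a-5p, from the same transcript as miR-143, was at −0.11 (−0.22 to 0.035 with 1 library left out) and its passenger arm miR-145a-3p at −1.75 (edgeR adjusted p = 0.88 and 0.079; the latter passed without ET1 library 1, at −2.12). Camera gave an adjusted p of 0.0089, but adjusted p = 0.38 with an estimated correlation, within a range of 0.0079 to 0.38 over 19 alternatives. Without untreated library 1, ET1 library 1 or ET1 library 3 the list did not pass. Its mean difference to the other miRNAs, −0.99 with all libraries, was −0.64, −0.74 and −0.54 in these fits. In all 6 fits without 1 library the difference was nearer to 0 (−0.79 to −0.54). The filter then kept 631 to 677 miRNAs in place of 616, so the tested rows changed as well. Nor did the list pass with the share of miRNA tags as a covariate (−0.55) or under the filter of at least 10 CPM in 3 libraries.

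The epithelial and Sertoli list also lay lower in these ET1 libraries with the lower miRNA and higher rRNA share, with 13 of 16 tested members negative and a median of −0.80. None of its members passed, over all miRNAs or over the list alone. miR-183-5p, of the sensory and epithelial miR-183 cluster, stood at 105 ± 27.6 against 201 ± 63.5 CPM (−0.94; edgeR adjusted p = 0.24), and miR-200b-3p, which maintains the epithelial state, at 36.3 ± 12.8 against 72.2 ± 50.7 CPM (−0.99; edgeR adjusted p = 0.36), or −0.25 without untreated library 2. miR-202-3p, a gonadal miRNA of Sertoli cells and the most abundant member, was at 0.052 (1143 ± 579 against 1103 ± 245 CPM), and this sign changed without a filter and in limma-voom. Camera gave an adjusted p of 0.010, but adjusted p = 0.38 with an estimated correlation, within a range of 0.0022 to 0.96 over 19 alternatives. Without untreated library 2 the mean difference was −0.47 in place of −0.74 and the list did not pass. Nor did it pass under the filter of at least 10 CPM in 3 libraries (−0.61, camera adjusted p = 0.082). With the share of miRNA tags as a covariate the mean difference was 0.063.

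The let-7 family, whose members restrain proliferation and stem cell genes, had 15 of 20 tested members negative, with a median of −0.39, and none passed over all miRNAs or over the list alone. Its share of known miRNA tags was 40.7% ± 3.31 in ET1 and 43.3% ± 5.72 in untreated libraries (n = 3 each; exact permutation p = 0.6). let-7f-5p had the lowest log2 fold change of the family, −1.37 (−1.69 without untreated library 3, where it passed). let-7f-2-3p, at a mean of 1.53 CPM, had the highest, 0.68 (0.43 to 1.05 with 1 library left out). Counts of single members are uncertain, because the sequences are near-identical. Camera gave an adjusted p of 0.044, but adjusted p = 0.54 with an estimated correlation, within a range of 0.015 to 0.96 over 19 alternatives. Without untreated library 1, untreated library 2, ET1 library 1 or ET1 library 3 the list did not pass (camera adjusted p 0.11, 0.061, 0.054 and 0.10). Nor did it pass under the filter of at least 10 CPM in 3 libraries. In the ET1 libraries the share of known miRNA tags was lower and that of rRNA fragments higher. With the miRNA share as a covariate the mean difference to the other miRNAs was −0.19 in place of −0.49 and the list did not pass.

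With all 6 libraries the other lists did not pass. In the haematopoietic list miR-150-5p fell, while miR-342-3p, its most abundant member, was at −0.79 (−1.24 to −0.39 with 1 library left out), miR-451a, a red cell miRNA, at −0.56 (−1.10 to 1.45) and miR-223-3p, a myeloid miRNA, at 0.29 (−0.12 to 1.28; camera adjusted p = 0.054; 5 tested, 4 negative); the list passed with library sizes alone (mean difference −1.05, as with TMM) and without the 16 rows that differ from the pooled counts (−1.06). With 1 library left out, when 6 members were tested, its mean difference ran from −0.89 to −0.36 (without untreated library 3) and it did not pass. The endothelial list had 2 tested arms and no test, with miR-126a-5p at 1.52 ± 0.517 against 6.19 ± 1.46 CPM (log2 fold change −2.01; edgeR adjusted p = 0.079) beside miR-126a-3p. In the stimulus-responsive list, 12 of 17 were negative (camera adjusted p = 0.065), with miR-155-5p, an inflammatory miRNA, at 1156 ± 445 against 3070.04 ± 1264 CPM (−1.41; edgeR adjusted p = 0.086), or −1.79 without ET1 library 1, where it passed, as it did without untreated library 3. That list passed without untreated library 3 or ET1 library 1, with mean differences of −0.83 and −0.72 in place of −0.52, and without a filter (−0.47). In the mesenchymal list 19 of 25 were negative and miR-10b-5p fell (camera adjusted p = 0.14), with miR-22-3p the most abundant member. All 5 tested members of the miR-290 to miR-295 group, miRNAs of pluripotent and germline cells, were positive (camera adjusted p = 0.10), with miR-292a-3p at 0.83 (0.45 to 1.43 with 1 library left out). The group passed without untreated library 2 or ET1 library 3, with a mean difference of 1.38 in each in place of 0.76, and without a filter (1.31).

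The spermatogenic list had 12 positive and 15 negative members (camera adjusted p = 0.81); its median was −0.21, its mean 0.062 and the direction of the test was down, so the signs differed. Its most abundant member was miR-470-5p, and none of its members passed. miR-449a-5p, of multiciliated and meiotic cells, stood at 182.7 ± 158 against 46.1 ± 10.6 CPM (1.99; edgeR adjusted p = 0.086); it passed without ET1 library 1 (2.34) and was at 1.0004 without ET1 library 3. In the miR-17-92 list, a proliferation-associated family, 10 of 15 were negative (camera adjusted p = 0.25), with miR-92a-3p at −0.81. In the non-canonical list 5 of 8 were positive (camera adjusted p = 0.30), with miR-320-3p at −0.21 (−0.37 to −0.039 with 1 library left out), or 0.15 with library sizes alone. Of 6 tested miRNAs of other tissues 4 were positive (camera adjusted p = 0.49), with the liver miRNA miR-122-5p at 0.81 (0.22 to 1.35 with 1 library left out); without ET1 library 1 this list passed, at a mean difference of 1.46 in place of 0.48. By fry none of the 12 lists passed.

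**Figure D3:**
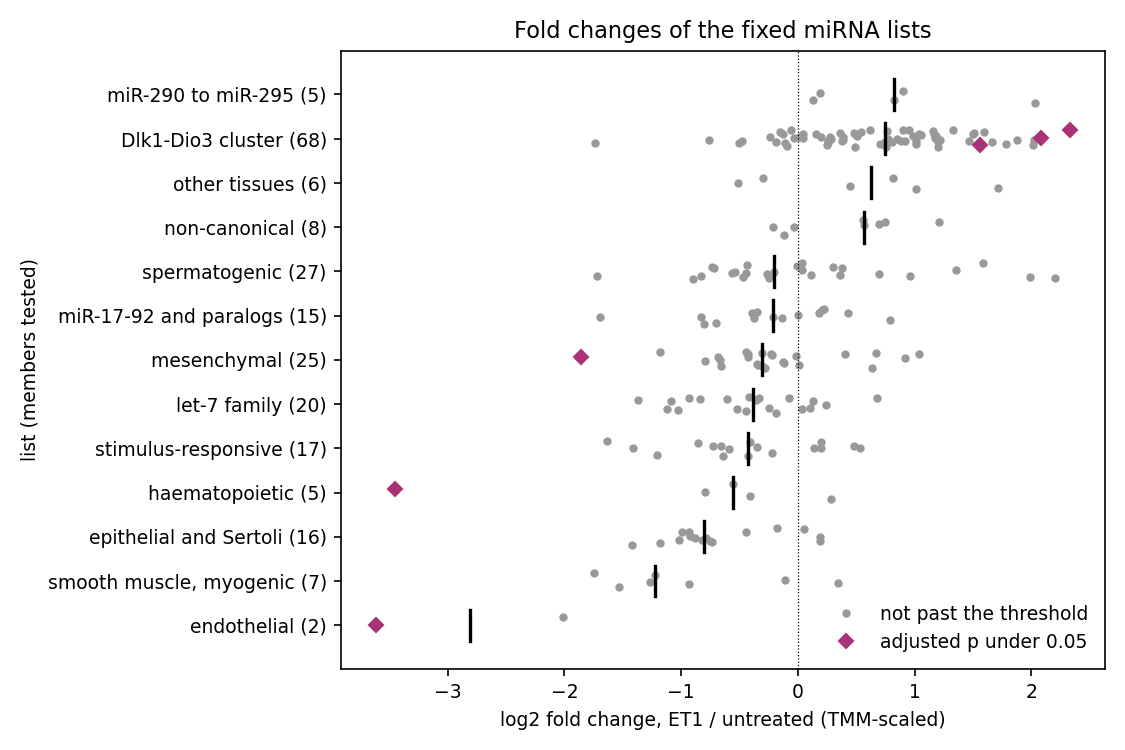
Log2 fold change (ET1 over untreated) of the tested members of the 13 fixed lists, with a point per miRNA, purple diamonds for those past an adjusted p of 0.05 and black lines at the list medians. The Dlk1-Dio3 cluster has a median of 0.75 and the smooth muscle and myogenic list one of −1.23.

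Among the 2579 piRNA, Rfam and predicted rows tested, edgeR called 0 at the threshold, with 7.72% at an unadjusted p under 0.05; limma-voom also called 0. DESeq2 called 111, 39 higher and 72 lower in ET1 libraries, of which 82 were predicted piRNAs and 71 had no tag in any library of one of the groups. Simulated changes of 4 log2 units were recovered by edgeR in 44.2% of the changed rows that passed the filter. The absence of calls therefore does not bound changes of that size or smaller, and larger changes were not simulated.

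The authors' deposited table, which compared counts pooled over libraries, gave 774 known miRNAs a q-value under 0.05, 550 higher and 224 lower after ET1. All 11 miRNAs called by edgeR were among them. In the authors' deposited table, the highest log2 ratios under the naming rule were those of miR-3473e (4.56), miR-1199-3p (3.21), miR-486a-5p with miR-486b-5p (2.80), miR-5126 (2.80) and miR-3072-5p (2.72). The lowest in the authors' deposited table were miR-7688-5p (−5.81), miR-3074-5p (−5.35), miR-126a-3p (−3.28), miR-150-5p (−3.09) and miR-669c-5p (−2.17). miR-3473e, miR-3074-5p and miR-669c-5p did not pass in edgeR (adjusted p = 0.47, 0.35 and 0.49), and miR-7688-5p was removed by the filter. For miR-3473e the log2 fold change was 4.22 in edgeR with all libraries and −1.59 without ET1 library 1, and for miR-3074-5p the fits without 1 library ranged from −6.35 to −0.56. For miR-669c-5p they ranged from −3.07 to −0.39, the latter without untreated library 2. The log2 ratios of the authors' deposited table and of edgeR had a Spearman correlation of 0.97 across 616 miRNAs, which are not independent replicates and come from the same libraries, and the deposited ratio was higher by a median of 0.35. With that offset 66 of the 525 deposited calls tested by edgeR had the opposite sign there.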

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

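The GC corrections, the covariate fit and the fits with fewer kinds of rows were chosen after the data were seen. Of the 11 calls, miR-126a-3p and miR-150-5p passed in 18 of their 20 alternatives, with the exceptions of the covariate fit and the fit of all rows together. The number of known miRNAs past the threshold, 11 as reported, was 41 with library sizes alone (38 higher, 3 lower), 37 without a filter (22 higher, 15 lower), 39 in DESeq2 (24 higher, 15 lower), 3 without robust estimation (1 higher, 2 lower), and 0 with the miRNA share as a covariate and with all rows fitted together. It was 11 with DESeq2 size factors, 14 in limma-voom, 14 with the GC correction (8 higher, 6 lower; 8 of the 11 among them), and from 2 to 30 when 1 library was left out: 11 without untreated library 1 (8 higher, 3 lower), 5 without untreated library 2 (2 higher, 3 lower), 25 without untreated library 3 (15 higher, 10 lower), 30 without ET1 library 1 (21 higher, 9 lower), 9 without ET1 library 2 (4 higher, 5 lower) and 2 without ET1 library 3 (both lower). Among the other rows, 0 calls became 34 without a filter and 111 in DESeq2, and stayed 0 in each fit without 1 library. The number of lists, 4 as reported, was 7 without a filter, 1 with at least 10 CPM in 3 libraries, 2 with the covariate, 0 with an estimated correlation and 0 by fry, and from 2 (without untreated library 1) to 5 with 1 library left out. The edgeR calls shared with the authors' deposited table numbered 41 at an adjusted p under 0.1. The differences in the share of known miRNA, rRNA and top 10 tags kept their sign with 1 library left out, and that of the top 10 ran from −1.75 (without untreated library 3) to −0.19 points (without untreated library 2).

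With the replicate number as a block, 21 known miRNAs passed (14 higher, 7 lower), the 11 among them, and 41 with the block and the GC correction (17 higher, 24 lower). Deviations from the group means correlated between same-numbered libraries at 0.28, 0.060 and 0.25 across miRNAs. Each untreated library correlated best with the ET1 library of its own number. The labels state no pairing, so the numbers were not taken to pair the libraries, but a pairing is not excluded.

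Changes of sign, or of the direction of a list's test alone, were found for items that had not passed, except for the epithelial and Sertoli list. With library sizes alone, log2 fold changes became 0.039 for let-7b-5p, 0.0013 for miR-181a-5p, 0.0039 for miR-34a-5p, 0.050 for miR-125b-5p, 0.22 for miR-127-3p and 0.15 for miR-320-3p. With the covariate, the list differences became 0.063 for epithelial and Sertoli, 0.0074 for stimulus-responsive, −0.0085 for mesenchymal (a change only in the direction of the test) and −0.22 for non-canonical. With the covariate, single log2 fold changes became 0.27 for let-7c-5p, 0.046 for miR-22-3p, 0.39 for miR-34a-5p, −1.54 for let-7d-3p, 0.0019 for miR-127-3p, 0.031 for miR-342-3p and 0.30 for miR-669c-5p. Without a filter they were 0.43 for the haematopoietic list, −0.030 for miR-470-5p and −0.035 for miR-202-3p. For the spermatogenic list, at 0.0045 as reported with the test pointing down, only the direction of the test changed with the difference at 0.13 without a filter, 0.092 under the filter of 10 CPM, 0.20 with the GC correction and 0.29 with the GC correction and block, and by fry at a mean of 0.062. The covariate gave it 1.09 (adjusted p = 0.0092, range over 19 alternatives 0.0092 to 0.97). miR-202-3p was at −0.052 with the block, −0.072 in limma-voom and −0.00098 with the GC correction and block. With all rows together, miR-470-5p was at −0.48, let-7d-3p at −0.20 and miR-202-3p at −0.45. Without 1 library, ranges that crossed 0 were −0.27 to 0.59 for the spermatogenic list, −0.41 to 0.44 for miR-470-5p, −0.25 to 1.07 for let-7d-3p, −0.45 to 0.13 for miR-127-3p, −0.40 to 0.36 for miR-202-3p and −1.59 to 4.78 for miR-3473e, and the list of other tissues ran from 0.18 to 1.46 with a change in the direction of the test. The ranges of miR-451a (−1.10 to 1.45), miR-223-3p (−0.12 to 1.28) and miR-145a-5p (−0.22 to 0.035) without 1 library crossed 0 as well. The cause of these changes was not tested, except that library sizes alone move all miRNAs of a library together. Each library held at least 4381927 known miRNA tags, but low counts limit single results: miR-3072-5p had 6, 8 and 12 tags in the untreated libraries.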

Other observations

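The tests of the miR-126a-3p and miR-150-5p pattern, the counts of splits for the miRNA and other-row calls, the GC corrections, the covariate fits, the let-7 arms of at least 10 CPM that match the pooled counts and the chance level of arm agreement were chosen after the results they bear on were seen. In the let-7 family the arms parted: the 9 tested 5p arms had a median log2 fold change of −0.94 (from −1.37 to −0.33) and the 9 tested 3p arms one of 0.034 (from −0.36 to 0.68; exact permutation p = 0.0029 for the difference of medians, over members that share tags and are not independent). Of the 3p arms, 5 lay below 5 CPM, let-7f-2-3p at the upper end among them, and let-7b-3p at the lower end is one of the rows whose counts differ from the pooled ones. The 3 other 3p arms ran from −0.074 to 0.099 (exact permutation p = 0.023 against the 5p arms), let-7d-3p at 0.099 beside let-7d-5p at −0.84. Tags assigned to the mir-133 precursor family, chosen after its values were seen, numbered 4218, 3133 and 3649 in untreated libraries and 1042, 1037 and 960 in ET1 libraries (DESeq2 adjusted p = 1.25e-06, edgeR adjusted p = 0.28), beside miR-133a-3p at −1.53 on the scale of the known miRNAs. Those of the mir-92 family numbered 26467, 22374 and 33755 against 15063, 8821 and 13941 (DESeq2 adjusted p = 2.29e-09, edgeR adjusted p = 0.28), beside miR-92a-3p at −0.81. These counts are not scaled, and the share of known miRNA tags was lower in the same libraries.

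miR-126a-3p and miR-150-5p lay far lower in the ET1 libraries. A fall as large as that of miR-150-5p was not seen in the other tested haematopoietic members, miR-342-3p, miR-342-5p, miR-451a and miR-223-3p. The median of these members was −0.48 (SD 0.46) against −3.45 for miR-150-5p. They are weak evidence on blood-derived cells. miR-342-3p and miR-342-5p are arms of a single precursor, and miR-223-3p was at 8.88 ± 7.65 CPM in untreated libraries. With all libraries no arm of miR-142a or miR-144 was tested, so fewer blood-derived cells are not excluded. With 1 library left out the median ran from −0.75 to −0.20, with an SD of up to 1.01 (without untreated library 3). With the miRNA share as a covariate these members ran from −2.94 to 2.21 (SD 2.11). Levels of the most abundant were 335 ± 160 against 581 ± 248 CPM for miR-342-3p and 184 ± 133.8 against 270.1 ± 350 CPM for miR-451a. For miR-150-5p, fewer lymphocytes alone cannot be told apart from an effect of ET1. The members compared include a red cell miRNA (miR-451a) and a myeloid one (miR-223-3p). The choice among these scalings shifts all miRNAs together and by too little to explain the pair. The median of all tested miRNAs was 0.0058 with TMM and 0.37 with library sizes alone. The value nearest to 0 of the pair under size factors or library sizes alone was −3.08. Fewer endothelial cells in the ET1 cultures may explain miR-126a-3p and cannot be told apart from an effect of ET1. The only other tested arm, miR-126a-5p, was at −2.01 without passing. It comes from the same precursor and could fall under either account, so its value does not decide. The list holds no further tested member, and no member of the endothelial or haematopoietic list is in another list. An effect of ET1 within 5 min remains an untested hypothesis. Here and in the patterns below, other differences between the cultures or libraries of the groups cannot be told apart from it.

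The Dlk1-Dio3 miRNAs lay higher in the ET1 libraries. A bias that follows precursor GC content is argued against as the whole cause. The mean difference to the other miRNAs was 0.73 after the GC correction and 0.71 before it. The GC content of the tags themselves was not used. The lower share of miRNA tags cannot be told apart from ET1, because the share follows the groups. With that share as a covariate the difference was 0.88, so it did not shrink. Capture of single arms cannot be told apart from a change of the whole precursors, because 70.8% of the 24 precursors with both arms tested had the arms on the same side of the median (17 of 24), where unrelated arms would give 74.3%, so that the 50% set as chance beforehand was wrong and the test decides nothing. A change of the cluster with ET1 stays open as a hypothesis.

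The let-7 family lay lower in the ET1 libraries. A loss of let-7 precursors that lowers both arms alike is argued against by the 3p median of 0.034 with all libraries. This median was below 0 with the GC correction (−0.14, against −0.80 for the 5p arms) and without untreated library 2 (−0.18, against −0.68). It was also below 0 without ET1 library 2 (−0.056) or ET1 library 3 (−0.10). Over the 3p arms of at least 10 CPM that match the pooled counts (n = 3) it was −0.16 with the GC correction. Without untreated library 2 it was −0.21 over these arms (exact permutation p = 0.082). With the covariate these 3p arms lay below the 5p arms (−0.78 and 0.17). GC content could account for part, since the difference to the other miRNAs was −0.49 before and −0.41 after the GC correction, where it no longer passed (adjusted p = 0.061). The share of miRNA tags cannot be told apart from ET1, since the difference was −0.19 with the covariate and the share follows the groups. An effect of ET1 on the 5p arms, or tags shared between near-identical 5p arms, stays open.

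The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 11 known miRNAs and the highest other split 1, so that 1 of 10 splits gave as many. For the other rows the real split gave 0, as did the others (10 of 10). For the lists the real split gave 4 and the highest others 6, with 3 of 10 as large; both splits with 6 set untreated libraries 1 and 2 with an ET1 library against untreated library 3 with the other ET1 libraries.

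On the first principal component of the known miRNAs, which held 36.3% of the variance, untreated library 3 (−2.3) and ET1 library 1 (5.49) were the nearest libraries of opposite groups, but on the second they lay farthest apart (−13.1 and 17.4). The known miRNA share of untreated library 3 (30.1%) was the lowest of its group. Of the 577 predicted piRNAs with at least 100 tags in some library, 65 (11.3%) had 0 tags in at least 1 library, against 0.752% of known miRNAs. Of 1989 predicted piRNAs with at least 30 tags in total, 80 were present in all 3 libraries of a group and at 0 in all 3 of the other, and up to 53 in the other splits. Pooled and per-library counts differed in 16 rows; miR-328-3p, for example, had 19, 27161 and 48808 tags in untreated and 9, 4 and 21471 in ET1 libraries, against pooled counts of 97239 and 72904 in the authors' deposited table, while in miR-712-5p the sums, 115 and 42, were above the pooled 19 and 25.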
